A study of Mus musculus with 14 samples.

How the data were processed

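The samples are 14 libraries of bulk RNA from activated CD4 T cells of C57BL/6 mice. Naive CD4 cells had been kept in culture for 3.5 days on plates coated with antibodies against CD3 and CD28, under the condition that names each group, and were then stained, sorted by flow cytometry into Trizol LS and lysed there. Libraries were made from 100 ng of RNA with the Lexogen SENSE mRNA kit. Groups and replicate numbers come from the sample titles: Th1 (5 libraries), TfhA (4, without a replicate 3) and Tfh5 (5), TfhA with TGF-β blocked and Tfh5 with 5 ng/ml TGF-β. Whether libraries came from separate animals, cultures or days, and what a replicate number stands for, is not given in the sources used here.

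The deposited values are raw counts per gene under Entrez gene identifiers, with no normalization. The submitters' notes name STAR 2.7.2b, featureCounts 1.6.4 and the genome build mm10. The strand setting, the annotation and the treatment of reads that map to several places are not given in the sources used here. Levels of genes with near-identical copies, such as granzymes, guanylate-binding proteins, serpins, some mitochondrial genes and Gapdh, therefore depend on an unknown setting. The series table was checked against the 14 files of single samples and was identical, with 0 columns of other samples. It holds 27179 genes, of which 25275 have a symbol in the RefSeq annotation of mm10, 1904 have none and hold 1.91% of all counts, and 7667 have no count in any library. Genomic positions come from the same annotation.

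Library totals run from 8805921 to 16108059 counts. Replicates differed by more than counting error, with a chi-square per degree of freedom of 4.26 to 32.48 over 26 pairs of libraries within groups, taken on genes with at least 10 counts. The common biological coefficient of variation was 14.25%. Precision is therefore given as the SD between libraries or the SE of the fit. For genes with 1 to 3 counts over a whole group, a ratio with its 95% counting interval is given, and for genes with 0 counts a lower bound against a floor of 3 counts over the group.

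All values were computed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Counts of all 14 libraries entered one edgeR fit with group means and no covariate. Genes were kept by filterByExpr (13075 genes), libraries were scaled with TMM, and the 3 comparisons (Tfh5 minus TfhA, TfhA minus Th1, Tfh5 minus Th1) were tested with the quasi-likelihood F test, two-sided. A gene passed at an adjusted p under 0.05 (Benjamini-Hochberg over all tested genes), and the number that also differed by at least 2-fold is given. CPM are scaled by TMM, log2 CPM carry a prior count of 2, and the SE of a log2 fold change is its size divided by the square root of F. Principal components and correlations between libraries used log2 CPM. Library measures were compared with exact permutation tests over all regroupings of the 2 groups.

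Gene lists were written from general knowledge of T cells before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes, apart from the additions named as such. The 27 lists cover follicular helper, Th1, Th17, regulatory T, and Th2 and Th9 cells, TGF-β and SMAD response, genes linked to c-Maf, IL-2 and STAT5, IL-6 and STAT3, type I interferon and interferon-γ responses, cell cycle, naive and memory cells, inhibitory receptors and T cell receptor response, chemokine receptors and integrins, glycolysis, cholesterol synthesis, unfolded protein and amino acid stress, CD8 and NK cells, γδ T cells, B cells, monocytes with macrophages and dendritic cells, granulocytes and mast cells, red cells and platelets, mitochondrial genes, immediate early and heat shock genes, and nuclear and histone transcripts. Of 484 listed names, 481 are in the table. The 24 lists with at least 5 tested genes were tested against the other genes with camera at its preset correlation of 0.01, adjusted over lists and comparisons together. Camera with an estimated correlation and fry stand beside it.

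Genes named in the text follow a fixed rule with 5 parts. The first is a panel of 26 genes, of which 25 could be tested. The second takes, per comparison, the 10 highest and 10 lowest log2 fold changes among genes that passed, with at least 10 CPM in the higher group, no overlap between the groups' libraries, and a symbol that is not a predicted gene, clone, pseudogene or antigen receptor segment. The third takes up to 4 called members per list with at least 5 CPM in a group, ordered by size of change. The fourth takes up to 2 of the most abundant members of a list with none called, read as none called at that level. The last takes 5 genes per direction for each group set apart from both others, with the same level and symbol limits. Outside this rule and chosen after their values were seen were Gzmb in the comparison of TfhA with Th1, the single markers named in the weighing of other cell types, and the Tfh5 genes counted in Th1 replicate 2. Results of 2 genes that the rule chose are not reported here, for a reason unrelated to their values.

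The steps were tested on simulated data made from these libraries, with 100 genes changed 1.5-fold and 100 changed 2-fold per comparison. The fit recovered 51, 55 and 54% of the former and 82, 81 and 76% of the latter for Tfh5 with TfhA, TfhA with Th1 and Tfh5 with Th1, with 3, 6 and 8 false calls (2.2, 4.2 and 5.8% of calls). These shares are of single genes and do not cover the list tests. Camera was also run there on lists of changed and of unchanged genes, and its p fell under 0.05 for an unchanged list too.

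Alternatives chosen beforehand were median-ratio and upper-quartile scaling, no filter on low counts, a filter of at least 5 CPM in at least 4 libraries, DESeq2, limma-voom, replicate number as a block, each pair of groups fitted alone, a test against a minimum fold of 1.5, the other list tests, other sets of genes for distances and pairing, and each library left out in turn. A correction for transcript GC content (a lowess trend per library as an offset, for the 96.8% of tested genes with a GC value) and a fit without Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5 were added after the data were seen. Numbers of calls were set against 100 regroupings of the libraries. Reads, splicing, alleles and protein levels were not analysed here, since the deposited processed files hold gene counts.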

Results

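The series holds bulk RNA sequencing of mouse CD4 T cells from C57BL/6 animals, activated in culture under 3 conditions. Th1 cells form the first group (5 libraries). TfhA names cells cultured toward follicular helper T cells, the CD4 cells that help B cells in germinal centres, with an antibody that blocks TGF-β (4 libraries, replicates 1, 2, 4 and 5). Tfh5 names the same kind of culture with 5 ng/ml TGF-β (5 libraries). Each library gave one count per gene, with totals from 8805921 to 16108059 counts and means (± SD) of 14500313 ± 1099408 in Th1, 10679262 ± 1927622 in TfhA and 10968996 ± 1360493 in Tfh5. Expression levels are counts-per-million values (CPM) as mean ± SD, with n = 5 for Th1, n = 4 for TfhA and n = 5 for Tfh5 throughout. Log2 fold changes carry ± SE from the edgeR fit, and adjusted p-values are two-sided with the Benjamini-Hochberg method over 13075 tested genes. The labels do not say whether libraries came from separate animals or cultures, so each p-value measures only the spread between these samples. Intervals and lower bounds for genes with 0 to 3 counts in a group cover counting error only.

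The 14 libraries separated by culture condition. The first principal component carried 80.9% of the variance of the 500 most variable genes and the second 15%. Correlations of log2 CPM between libraries of one group were 0.985 to 0.991 in Th1, 0.977 to 0.988 in TfhA and 0.970 to 0.984 in Tfh5. Between groups they were 0.916 to 0.943 for Th1 with TfhA, 0.872 to 0.893 for TfhA with Tfh5, and 0.834 to 0.856 for Th1 with Tfh5. The share of counts from the mitochondrial genome was higher in Tfh5 (8.03% ± 0.594) than in TfhA (5.82% ± 1.30) and Th1 (5.91% ± 0.871), with no overlap between Tfh5 and either group (exact permutation test, two-sided, p = 0.00794 each, 0.0136 after adjustment over 12 such tests). This share covers only part of that genome, since mt-Nd4l, mt-Co2, mt-Co3, mt-Atp6 and mt-Atp8 reached at most 0.526 CPM in any library. Why these genes had almost no counts was not tested.

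**Figure D1:**
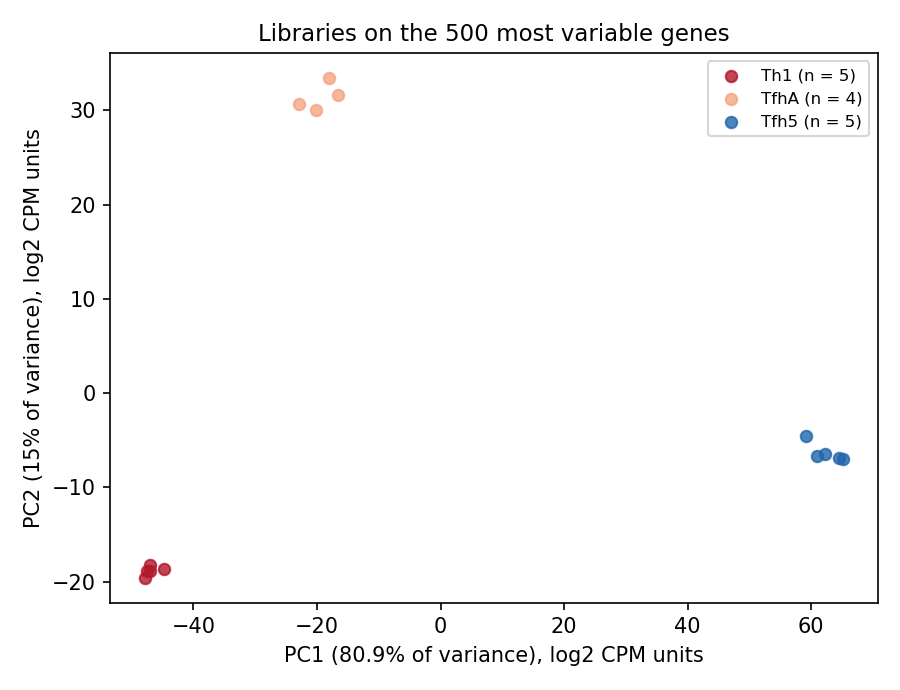
Principal component 1 (80.9% of variance) against principal component 2 (15%) of log2 CPM for the 500 most variable genes, with one point per library coloured by group. Th1, TfhA and Tfh5 libraries occupy 3 separate regions, and within-group correlations are 0.970 or higher.

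The comparison of Tfh5 with TfhA shows which transcripts differed between TGF-β and its blockade in the same kind of culture. The series title names TGF-β, follicular helper and Th17 cells and the transcription factor c-Maf as its subject. Tfh5 cells had far more transcript of Maf, which encodes c-Maf (1419 ± 153 CPM against 31.7 ± 3.03, 44.8-fold higher, log2 fold change 5.49 ± 0.18). They also had more transcript of the interleukin-17 genes Il17a (317 ± 48 against 0.428 ± 0.209 CPM) and Il17f (3274 ± 352 against 15.1 ± 4.57 CPM). The follicular helper regulator Bcl6 rose 6.36-fold and the follicle-homing receptor Cxcr5 40.1-fold. The Th1 regulator Tbx21 (32.6-fold lower) and the cytokine Ifng (20.2-fold lower) fell, as did all 26 cell cycle genes (camera adjusted p = 2.83e-12, adjusted p = 0.0197 with an estimated correlation). Of the tested genes, 7520 passed the threshold, 3586 higher and 3934 lower in Tfh5, and 1381 of the higher and 1716 of the lower ones differed by at least 2-fold.

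Of the 25 panel genes that could be tested, 14 were higher in Tfh5, 9 were lower and 2 did not pass, with the same counts adjusted over the list alone. In 22 of the 25, called or not, the 2 groups did not overlap, which chance gives for 1.59% of unchanged genes at these group sizes. Of all tested genes 57.5% passed, and their share without overlap is not given here, so the panel is not shown to differ from other genes. Maf (Entrez gene 17132) lies on mm10 chromosome 8, 115703253 to 115706894. Besides the genes above, Tcf7, a transcription factor of naive and follicular helper cells, rose 3.16-fold (2080.4 ± 135 against 658 ± 117 CPM), and Smad7, an inhibitor induced by TGF-β signalling, rose 6.4-fold. Rora rose 5.36-fold, the integrin gene Itgae 8.39-fold, Sh2d1a 2.2-fold, the cytokine Il21 1.94-fold and the receptor Pdcd1 1.64-fold. Il10 was 25.7-fold higher (9.56 ± 1.39 against 0.323 ± 0.342 CPM), and 46.2-fold without TfhA replicate 1. Prdm1, which encodes the repressor Blimp-1 that opposes Bcl6, fell from 3.76 ± 0.971 to 0.13 ± 0.11 CPM (27.5-fold), Cxcr3 13.9-fold and Eomes 6.54-fold. Smaller decreases were measured for Gata3 (1.82-fold), Icos (1.7-fold) and Il2ra (1.43-fold), and Il4 was 4.42-fold lower at about 1 CPM (6.63-fold without Tfh5 replicate 4). The call of Il4 was lost without Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5 together (log2 fold change -1.71 ± 0.84 against -2.14 ± 0.61, adjusted p = 0.0972, within 0.00115 to 0.0972 over alternatives). Foxp3 (log2 fold change 0.89 ± 0.43, adjusted p = 0.0819) and Ccr7 (0.02 ± 0.11, adjusted p = 0.92) did not pass. Foxp3 did pass without TfhA replicate 4 (0.043), with no filter on low counts (0.037) and with replicate number as a block (0.00485, within 0.00485 to 0.405 over alternatives). Ascl2, the remaining panel gene, had 31, 17 and 9 counts in Th1, TfhA and Tfh5 and was not tested.

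**Figure D2:**
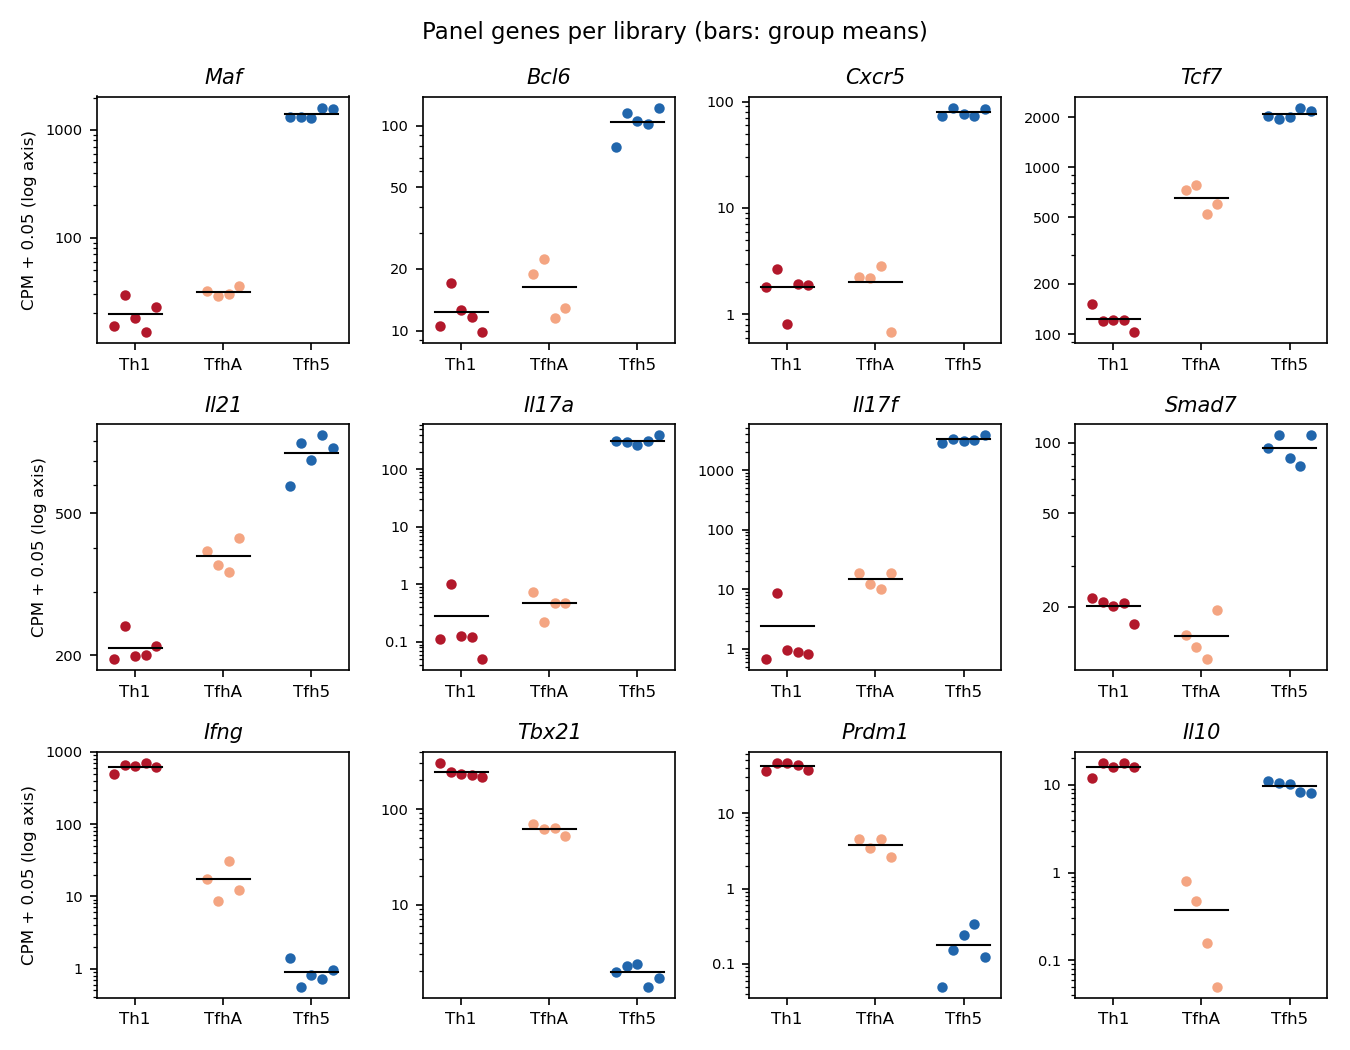
CPM (log axis, 0.05 added) of 12 panel genes in each library, with points for the 5 Th1, 4 TfhA and 5 Tfh5 libraries and bars at the group means. Maf is 1.61-fold higher in TfhA than in Th1 and 44.8-fold higher in Tfh5 than in TfhA, while Ifng, Tbx21 and Prdm1 fall from Th1 to TfhA and again to Tfh5.

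The 10 genes with the highest fold change by the fixed rule were Gja5, Daw1, Il17a, Ccl20, Myo3b, Gli3, Postn, Peli2, Gpr15 and Il17f. Ccl20, the ligand of the receptor Ccr6, reached 301 ± 27.7 CPM against 0.412 ± 0.181 (712-fold), and Myo3b, an unconventional myosin, 141 ± 18.9 against 0.25 ± 0.108 (537-fold). Il17a was 712-fold and Il17f 216-fold higher. Gja5, a gap junction protein, had no count in TfhA and 25 CPM in Tfh5, at least 356-fold higher against a floor of 3 counts over the group. Gpr15, a homing receptor for the large intestine, was 315-fold higher, and 702-fold without TfhA replicate 4. The 10 with the lowest were Dcn, Gzmc, Il3, Dgkk, Gzmb, Vat1l, Serpinb9b, Rtp4, Nkg7 and Il33. Gzmb, the cytotoxic protease granzyme B, fell from 1472 ± 226 to 4.97 ± 6.28 CPM (296-fold, and 642-fold without Tfh5 replicate 1), and Nkg7, a cytotoxic granule protein, 103-fold. The cytokine Il3 had 2 counts in Tfh5 and 21.5 CPM in TfhA, a ratio of 602-fold (95% counting interval 166 to 4980), and the matrix proteoglycan gene Dcn had none, at least 188-fold lower. Reads of Gzmb, Gzmc and Serpinb9b can be shared with near-identical relatives. Adjusted p-values of these 20 genes ran from 2.51e-19 to 3.55e-10.

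Among lists of helper cell genes, the Th1 genes fell together in Tfh5: 20 of 23 were lower and 2 higher (camera adjusted p = 5.88e-08, adjusted p = 0.0197 with an estimated correlation), with a median log2 fold change of -2.71, or -2.46 with the one gene at the count floor set to its bound. Ly6c2 (43.4-fold) and Twist1 (40.3-fold) were among the largest decreases. Of 20 Th17 genes, 14 rose and 4 fell (camera adjusted p = 9.48e-05, adjusted p = 0.0764 with an estimated correlation), including Il17re, an interleukin-17 receptor chain (21.9 ± 2.67 against 0.0805 ± 0.0933 CPM). Of 21 follicular helper genes, 13 rose and 7 fell, but the list as a whole did not pass (camera adjusted p = 0.141, adjusted p = 0.574 with an estimated correlation). Tox2 rose 8.51-fold while Tnfsf8, a TNF family ligand, fell 24.3-fold. The genes linked to c-Maf split 5 up and 5 down (camera adjusted p = 0.46, adjusted p = 0.694 with an estimated correlation), and the IL-6 and STAT3 list 8 up and 4 down (camera adjusted p = 0.146, adjusted p = 0.688 with an estimated correlation), with Il6st, the shared IL-6 receptor chain, 5.41-fold higher. In the TGF-β and SMAD list 13 of 21 rose and 6 fell (camera adjusted p = 0.0044, adjusted p = 0.0764 with an estimated correlation), among them Ldlrad4 (55.5-fold) and Skil (9-fold), both inhibitors of SMAD signalling. The regulatory T cell list gave 7 up and 10 down (camera adjusted p = 0.986, adjusted p = 0.997 with an estimated correlation). Its median was negative (-0.57) and its mean positive (0.40), with Nt5e, the ectoenzyme CD73, 81.9-fold higher (1525 ± 194 against 18.5 ± 3.82 CPM). Of 11 Th2 and Th9 genes, 9 fell and 1 rose (camera adjusted p = 0.0102, adjusted p = 0.0606 with an estimated correlation), the exception being the chemokine receptor Ccr8 (18.9-fold higher).

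Response and metabolic lists moved mostly down in Tfh5. None of 20 type I interferon response genes rose and 18 fell (camera adjusted p = 5.92e-09, adjusted p = 0.0606 with an estimated correlation), with a median log2 fold change of -3.96. Isg15 fell from 15.7 ± 3.16 to 0.364 ± 0.229 CPM (43.7-fold) and Mx1 46.8-fold, or 97.1-fold without Tfh5 replicate 1. Of 18 interferon-γ response genes, 14 fell and 1 rose (camera adjusted p = 2.05e-05, adjusted p = 0.0606 with an estimated correlation), with the guanylate-binding protein genes Gbp4 and Gbp7 15.4-fold and 14.7-fold lower. The cell cycle genes that fell included Tk1 (3.78-fold) and Top2a (3.27-fold). Of 20 glycolysis genes, 18 fell and none rose (camera adjusted p = 9.67e-07, adjusted p = 0.121 with an estimated correlation), with hexokinase Hk2 7.53-fold and the glucose transporter Slc2a3 4.38-fold lower. Of 21 cholesterol synthesis genes, 17 fell and none rose (camera adjusted p = 1.42e-05, adjusted p = 0.0637 with an estimated correlation), as Lss did 3.05-fold. Of 15 IL-2 and STAT5 response genes, 13 fell and 1 rose (camera adjusted p = 5.05e-05, adjusted p = 0.0639 with an estimated correlation), with the survival gene Bcl2 8.59-fold and the costimulatory receptor Tnfrsf9 6.68-fold lower. Of 18 genes of unfolded protein and amino acid stress, 15 fell and 1 rose (camera adjusted p = 0.000338, adjusted p = 0.0203 with an estimated correlation), among them Psat1 (2.94-fold) and Phgdh (4.41-fold), both of serine synthesis. Tfh5 libraries, in which these lists were lower, also had the higher mitochondrial share given above.

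Other lists that did not pass camera in this comparison included the naive and memory genes (8 up, 4 down of 15, camera adjusted p = 0.141, adjusted p = 0.317 with an estimated correlation), with Foxo1 3.11-fold higher, and the inhibitory receptor and T cell receptor response genes (7 up, 6 down of 17, camera adjusted p = 0.728, adjusted p = 0.933 with an estimated correlation, median 0.20 and mean -0.18), with Lag3 3.01-fold higher and Nr4a2 3.26-fold lower. Chemokine receptors and integrins gave 10 up and 10 down of 25 (camera adjusted p = 0.638, adjusted p = 0.697 with an estimated correlation), with Ccr6 8.48-fold higher. Immediate early and heat shock genes gave 3 up and 7 down of 15 (camera adjusted p = 0.443, adjusted p = 0.689 with an estimated correlation), with Jun 2.65-fold higher and Hsp90aa1 2.97-fold lower. Nuclear and histone transcripts gave 2 up and 1 down of 6 (camera adjusted p = 0.728, adjusted p = 0.821 with an estimated correlation, median 0.09 and mean -0.37), and mitochondrially encoded genes 5 up and none down of 8 (camera adjusted p = 0.128, adjusted p = 0.693 with an estimated correlation, 0.0488 by the first test without TfhA replicate 5), with mt-Cytb 1.56-fold higher.

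Markers of other cell types were mostly lower in Tfh5 than in TfhA. Of 11 B cell markers, 8 fell and 2 rose (camera adjusted p = 0.0473, adjusted p = 0.177 with an estimated correlation). This call was lost without Tfh5 replicate 2 or 5, without TfhA replicate 2 or 4, and without any one of the 5 Th1 libraries, at adjusted p from 0.0527 to 0.0667. Ebf1 fell 33.9-fold and Ighm rose 3.21-fold. Of 7 monocyte, macrophage and dendritic cell markers, 6 fell and 1 rose (camera adjusted p = 0.0136, adjusted p = 0.238 with an estimated correlation), among them Cd74 (8.76-fold), the invariant chain of MHC class II, and H2-Aa (at least 127-fold lower, with no count in Tfh5). CD8 T cell and NK cell markers gave 3 down and 1 up of 6 (camera adjusted p = 0.206, adjusted p = 0.306 with an estimated correlation, 0.0358 by the first test without TfhA replicate 5 and 0.0469 without TfhA replicate 2), with Klrk1 25.4-fold lower. Of 4 γδ T cell receptor genes tested, 3 fell and none rose, with Trdc 4.56-fold lower (11.8 ± 3.19 against 53.5 ± 19.3 CPM). One granulocyte marker could be tested, Ly6g, 3.13-fold higher, and one of red cells and platelets, Itga2b, at 1.36 ± 0.504 against 0.537 ± 0.261 CPM (adjusted p = 0.0251). The call of Itga2b was lost without Tfh5 replicate 5 (0.0705), TfhA replicate 1 (0.0937) or TfhA replicate 5 (0.0765), without Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5 together (0.0965) and with no filter on low counts (0.0559). In these fits the log2 fold change of Itga2b was 1.11 to 1.44, against 1.36 as reported. Adjusted over the list alone, the counts above were unchanged except for 8 up in the inhibitory receptor list, 11 up in the chemokine receptor list and 18 down in the cholesterol list.

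Each comparison was tested with the edgeR quasi-likelihood F test, and 13 of 24 lists passed camera in this one, 3 of them with an estimated correlation (Th1, cell cycle and unfolded protein lists).

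The comparison of TfhA with Th1 sets follicular helper culture with TGF-β blocked against Th1 culture. The cytokine Ifng fell from 623 ± 80.3 CPM in Th1 to 17.3 ± 9.97 in TfhA (36.3-fold, log2 fold change -5.18 ± 0.24), Tbx21 fell 3.96-fold and Prdm1 11.1-fold. Tcf7 rose 5.33-fold, Pou2af1, a coactivator of lymphocyte transcription, 71.6-fold (108 ± 29.5 against 1.53 ± 0.767 CPM) and Il2, the T cell growth factor, 24.2-fold. Bcl6 and Cxcr5 did not pass the threshold, and Maf rose 1.61-fold. Of 18 interferon-γ response genes 15 fell, and of 15 IL-2 and STAT5 response genes 12 fell and 1 rose (adjusted p = 0.0197 and 0.0452 with an estimated correlation). Of the tested genes, 5852 passed, 3031 higher and 2821 lower in TfhA, with 702 and 1084 of them differing by at least 2-fold.

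Of the 25 panel genes, 6 were higher in TfhA, 9 were lower and 10 did not pass, or 7, 9 and 9 adjusted over the list alone. In 12 of the 25, called or not, the groups did not overlap, against 1.59% of unchanged genes by chance. Since 44.8% of all tested genes passed, this does not show that the panel differs from other genes. Gata3 was 2.84-fold, Cxcr3 2.43-fold and Il21 1.81-fold higher. Il17f was 6.4-fold higher, and 19.2-fold without Th1 replicate 2, which held most of the Th1 counts of this gene. Il10 was 42.3-fold lower (76.3-fold without TfhA replicate 1), Sh2d1a 3.37-fold, Il2ra 2.81-fold, Icos 1.46-fold and Ccr7 1.28-fold lower. Smad7 was 1.35-fold lower (adjusted p = 0.0126, and 0.0566 without TfhA replicate 4). With GC-content correction the log2 fold change of Smad7 was -0.22 ± 0.14 in place of -0.43 ± 0.14, and the smaller change no longer passed (adjusted p = 0.209, within 0.00156 to 1 over alternatives). Among genes that did not pass, Bcl6 had a log2 fold change of 0.42 ± 0.18 with an adjusted p of 0.061. It passed at 0.0471 without Tfh5 replicate 1, 0.0181 without TfhA replicate 4, 0.032 without TfhA replicate 5 0.0138 without Th1 replicate 2, 0.0392 with no filter on low counts and 0.0449 with replicate number as a block (0.0138 to 1 over alternatives). Values for other genes that did not pass were 0.14 ± 0.29 for Cxcr5, 0.18 ± 0.14 for Pdcd1, -0.17 ± 0.26 for Rora, -0.13 ± 0.44 for Foxp3 and 0.58 ± 0.52 for Il4. Eomes (-0.61 ± 0.33) passed at 0.0334 without TfhA replicate 4, Itgae (0.73 ± 0.34) at 0.02 without TfhA replicate 5, 0.0329 without Th1 replicate 1 and 0.0289 without these 2 and TfhA replicate 2, and Il17a (0.84 ± 0.70) at 0.00158 without Th1 replicate 2.

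The 10 genes with the lowest fold change were Calca, Insl5, Onecut2, Casr, Stra6, Lrp1, Chl1, Cd83, Il10 and Sema3b, all with at least 10 CPM in Th1. Calca, which encodes calcitonin and CGRP, fell from 69.2 ± 8.42 to 0.499 ± 0.288 CPM (129-fold), Chl1, a neural adhesion molecule, from 191 ± 26.2 to 4.26 ± 0.927 (45.2-fold), and the activation marker Cd83 from 97.7 ± 10.8 to 2.19 ± 0.381 (44.6-fold). The 10 with the highest were Ndst3, Mab21l2, Pou2af1, Vat1l, Il33, Akr1c18, Moxd1, Dhrs9, Il2 and Scml4. Mab21l2 rose from 0.569 ± 0.132 to 44.7 ± 10.01 CPM (76.6-fold), Moxd1 43.5-fold and Scml4, a Polycomb group relative, 21.6-fold. The alarmin cytokine Il33 was 64.5-fold higher, or 127-fold without Th1 replicate 1. Adjusted p-values of these 20 genes ran from 2.28e-17 to 3.37e-09.

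Of 21 follicular helper genes, 12 rose and 4 fell (camera adjusted p = 0.00154, adjusted p = 0.177 with an estimated correlation), including Slamf6 (12.4-fold) and Angptl2 (9.75-fold). The Th1 list gave 10 down and 7 up of 23 (camera adjusted p = 0.0485, adjusted p = 0.267 with an estimated correlation), with Fasl 4.9-fold and Runx3 3.13-fold lower but Gzmb 2.53-fold higher. Its camera call was lost without each of Tfh5 replicates 1, 2, 4 and 5, TfhA replicates 2, 4 and 5 or Th1 replicates 2 and 5, at adjusted p from 0.0516 to 0.102, and with median-ratio scaling (0.055) or replicate number as a block (0.0548). Of 18 interferon-γ response genes, 15 fell and none rose (camera adjusted p = 1.29e-09, adjusted p = 0.0197 with an estimated correlation), with the transcription factor Irf8 25.9-fold and Iigp1 5.61-fold lower. Of 15 IL-2 and STAT5 response genes, 12 fell and 1 rose (camera adjusted p = 1.42e-06, adjusted p = 0.0452 with an estimated correlation), with lymphotoxin Lta 7.47-fold lower. Of 26 cell cycle genes, 21 rose and none fell (camera adjusted p = 1.43e-05, adjusted p = 0.0724 with an estimated correlation), with Top2a 1.81-fold and Ccna2 1.63-fold higher. Of 20 glycolysis genes, 14 fell and 2 rose (camera adjusted p = 0.000893, adjusted p = 0.291 with an estimated correlation), with Aldoc 2.89-fold and Aldoa 1.83-fold lower. In the TGF-β and SMAD list 12 of 21 fell and 3 rose (camera adjusted p = 0.0294, adjusted p = 0.16 with an estimated correlation, 0.0537 by the first test without TfhA replicate 4), with Skil 2.68-fold and Pmepa1 2.19-fold lower and Smad3 3.54-fold higher.

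B cell markers rose in 7 of 11 and fell in 1 (camera adjusted p = 0.00145, adjusted p = 0.0606 with an estimated correlation), at low levels, such as 11.7 ± 3.5 against 6.05 ± 0.808 CPM for Igkc, and Ebf1 was the gene that fell (1.7-fold). Its call was lost without Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5 together (log2 fold change -0.61 ± 0.27 against -0.77 ± 0.22, adjusted p = 0.0911, within 0.000203 to 0.366 over alternatives). All 4 γδ T cell receptor genes tested rose, with Trdc 9.58-fold higher (53.5 ± 19.3 against 5.54 ± 1.49 CPM) and Trgc4 25.8-fold, or 40.1-fold without Th1 replicate 3. Monocyte, macrophage and dendritic cell markers gave 2 up and 3 down of 7 (camera adjusted p = 0.986, adjusted p = 0.997 with an estimated correlation). Their camera direction was down although the median (0.89) and mean (0.67) were positive, with H2-Aa 18.7-fold higher but Cd74 2.89-fold and H2-Ab1 2.95-fold lower. Ly6g was 5.4-fold lower, and Itga2b was at 0.537 ± 0.261 against 0.576 ± 0.307 CPM (adjusted p = 0.867). CD8 T cell and NK cell markers gave 2 up and 1 down of 6 (camera adjusted p = 0.739, adjusted p = 0.786 with an estimated correlation), with Klrd1 2.42-fold higher.

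The type I interferon list split 8 up and 6 down of 20 (camera adjusted p = 0.821, adjusted p = 0.945 with an estimated correlation), with Ifih1, a sensor of viral RNA, 2.83-fold and Isg20 4.18-fold higher. Regulatory T cell genes gave 5 up and 10 down of 18 (camera adjusted p = 0.11, adjusted p = 0.532 with an estimated correlation), with Entpd1, the ectoenzyme CD39, 11.98-fold lower and Gpr83 8.53-fold higher. Th17 genes gave 3 up and 5 down of 20 (camera adjusted p = 0.383, adjusted p = 0.694 with an estimated correlation), with Il24 falling from 767 ± 96.1 to 21.6 ± 4.65 CPM (35.4-fold). Naive and memory genes gave 9 up and 5 down of 15 (camera adjusted p = 0.13, adjusted p = 0.306 with an estimated correlation), with the trafficking regulator Klf2 11.02-fold higher. Inhibitory receptor and T cell receptor response genes gave 9 up and 5 down of 17 (camera adjusted p = 0.289, adjusted p = 0.704 with an estimated correlation), with Egr2 5.07-fold and Cd160 14.2-fold higher. Chemokine receptors and integrins gave 8 up and 9 down of 25 (camera adjusted p = 0.956, adjusted p = 0.969 with an estimated correlation), with Ccr2 7.77-fold and the integrin Itga4 3.47-fold higher. Th2 and Th9 genes gave 3 up and 3 down of 11 (camera adjusted p = 0.986, adjusted p = 0.997 with an estimated correlation), with Areg 5.56-fold higher and Nfil3 4.13-fold lower. The other lists that did not pass were those linked to c-Maf (3 up, 3 down of 10, camera adjusted p = 0.898, adjusted p = 0.945 with an estimated correlation), with median 0.17 and mean -0.05, IL-6 and STAT3 (3 up, 4 down of 14, camera adjusted p = 0.927, adjusted p = 0.99 with an estimated correlation), cholesterol synthesis (7 up, 3 down of 21, camera adjusted p = 0.408, adjusted p = 0.697 with an estimated correlation) and unfolded protein (6 up, 2 down of 18, camera adjusted p = 0.296, adjusted p = 0.366 with an estimated correlation).

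In the immediate early and heat shock list 5 rose and 4 fell of 15 (camera adjusted p = 0.821, adjusted p = 0.908 with an estimated correlation), with Egr1 3.01-fold higher and Jun 3.16-fold lower. Nuclear and histone transcripts gave 3 down and none up of 6 (camera adjusted p = 0.458, adjusted p = 0.693 with an estimated correlation), as Neat1 did 1.53-fold (adjusted p = 0.0557 without Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5 together, within 1.39e-05 to 0.758 over alternatives). Without these libraries the log2 fold change of Neat1 was -0.52, against -0.61 as reported. One of 8 mitochondrially encoded genes rose and none fell (camera adjusted p = 0.995, adjusted p = 0.998 with an estimated correlation, median -0.06 and mean 0.05). Adjusted over the list alone, the counts in this comparison were the same except for follicular helper genes (13 up), Th17 genes (2 up), regulatory T cell genes (6 up), Th2 and Th9 genes (4 down), IL-6 and STAT3 genes (4 up), type I interferon genes (7 down), interferon-γ genes (18 down), glycolysis genes (15 down) and CD8 and NK markers (2 down). Camera passed 8 of 24 lists, and 2 of them held with an estimated correlation (IL-2 and STAT5, interferon-γ).

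**Figure D3:**
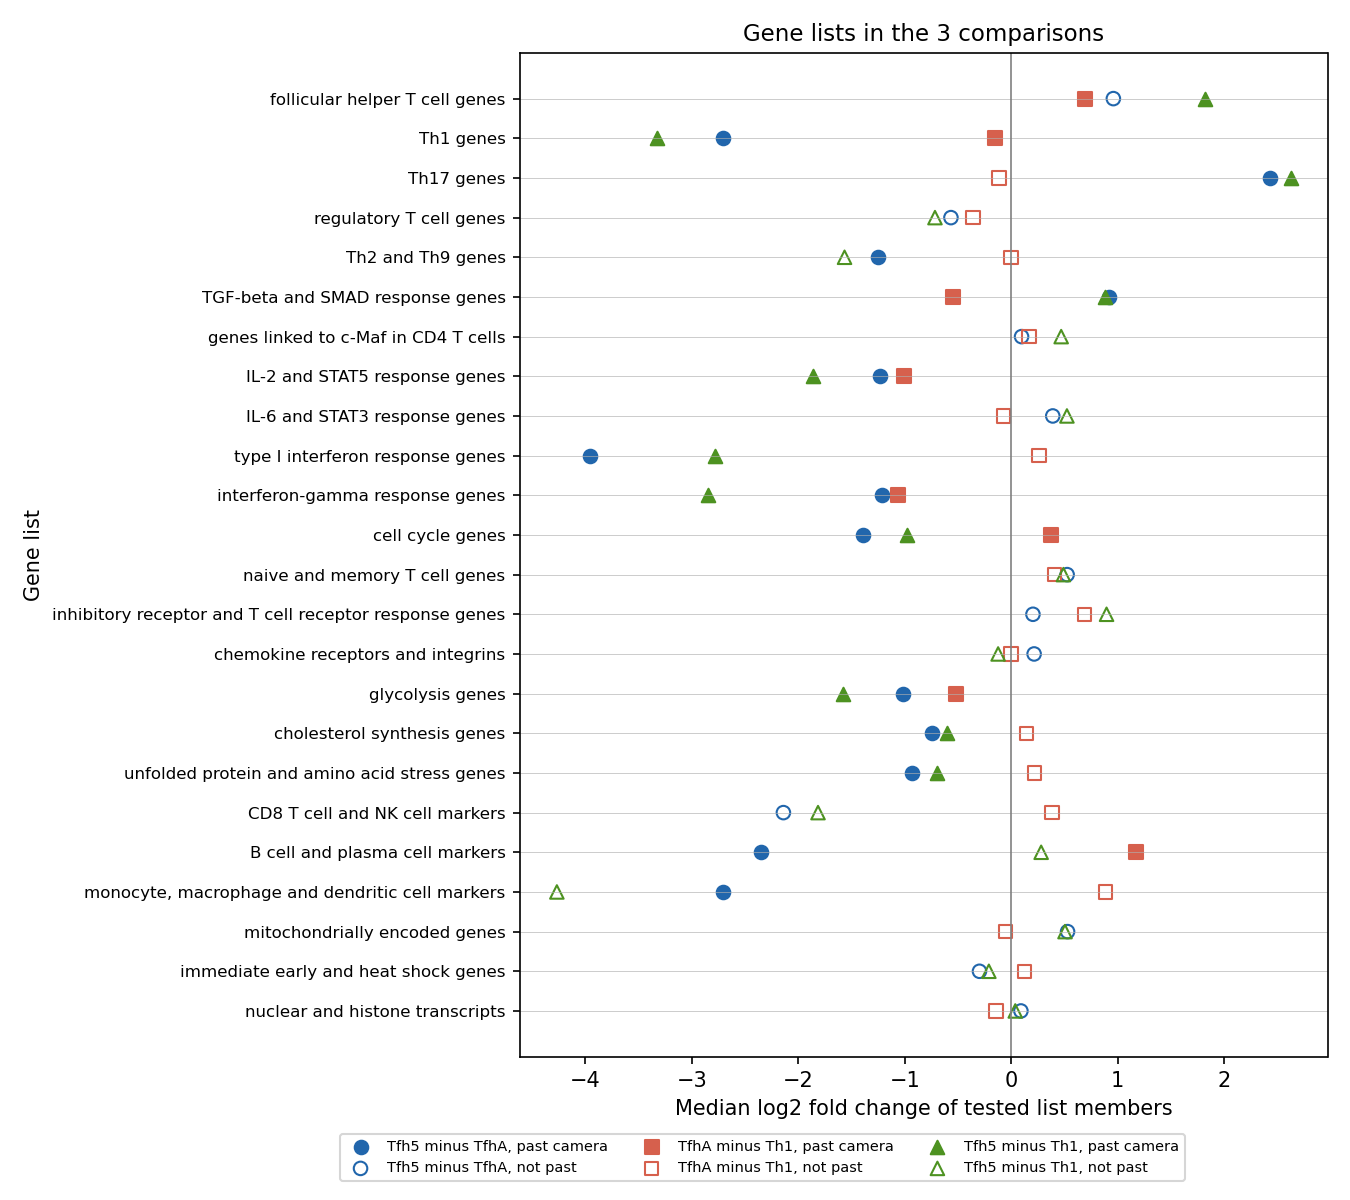
Median log2 fold change of the tested members of each of the 24 lists with at least 5 tested genes, for Tfh5 minus TfhA, TfhA minus Th1 and Tfh5 minus Th1, with filled points for lists past camera at an adjusted p under 0.05 and open points for the others. Medians are of fitted values, which for the monocyte, macrophage and dendritic cell markers in Tfh5 minus Th1 is -4.27, or -2.74 with genes at the count floor set to their bound. The type I interferon list has medians of -3.96, 0.26 and -2.79, and the cell cycle list -1.39, 0.37 and -0.98.

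The comparison of Tfh5 with Th1 sets follicular helper culture with TGF-β against Th1 culture, and held the largest number of changed genes of the 3 comparisons. Tbx21 fell from 244 ± 35.3 CPM in Th1 to 1.9 ± 0.424 in Tfh5 (129-fold, log2 fold change -7.01 ± 0.15) and Ifng from 623 ± 80.3 to 0.832 ± 0.313 (735-fold). Maf rose 72.3-fold, Cxcr5 44.3-fold, Tcf7 16.8-fold and Bcl6 8.53-fold. All 18 interferon-γ response genes, all 15 IL-2 and STAT5 response genes and 25 of 26 cell cycle genes fell (adjusted p = 0.0197, 0.0228 and 0.0452 with an estimated correlation). Of the tested genes, 8440 passed, 4119 higher and 4321 lower in Tfh5, with 1653 and 1994 of them differing by at least 2-fold.

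Of the 25 panel genes, 13 were higher, 11 were lower and 1 did not pass, with the same counts adjusted over the list alone. The groups did not overlap in 23 of the 25, called or not, against 0.79% of unchanged genes by chance. Here 64.6% of all tested genes passed, so the panel is again not shown to differ from other genes. Smad7 and Rora both rose 4.75-fold, Itgae 13.96-fold, Il21 3.52-fold, Pdcd1 1.86-fold and Gata3 1.56-fold. Il17a reached 317 ± 48 against 0.236 ± 0.412 CPM (1275-fold) and Il17f 3274 ± 352 against 2.34 ± 3.5 (1384-fold). Without Th1 replicate 2 these ratios were 5020-fold and 4170-fold. The first of them is imprecise, since Il17a was at 0 to 0.0756 CPM in the other Th1 libraries. Prdm1 fell from 42 ± 4.66 to 0.13 ± 0.11 CPM (304-fold), Eomes 10.004-fold, Cxcr3 5.71-fold, Il2ra 4.01-fold, Icos 2.49-fold, Il10 1.65-fold, Sh2d1a 1.53-fold and Ccr7 1.27-fold. Il4 was 2.96-fold lower (adjusted p = 0.0255). That call was lost without Tfh5 replicate 1 (0.0574), Tfh5 replicate 2 (0.0623), Tfh5 replicate 5 (0.0601) or Th1 replicate 2 (0.0506) and without Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5 together (0.0532), and without Tfh5 replicate 4 the difference was 4.45-fold. In the fits that lost the call, the log2 fold change of Il4 ran from -1.62 to -1.26, against -1.56 as reported. Foxp3 (log2 fold change 0.76 ± 0.39) had an adjusted p of 0.0926, or 0.0253 without Th1 replicate 4, 0.0465 with GC-content correction and 0.00915 with replicate number as a block (0.00915 to 0.361 over alternatives).

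The 10 genes with the lowest fold change were Gcnt4, Ifi211, Stra6, Chl1, Ifng, Il24, Cxcl11, Mt3, Fbn1 and Onecut2. Stra6, a receptor for retinol-binding protein, fell from 76.1 ± 14.1 to 0.0733 ± 0.0422 CPM (914-fold) and the interleukin-10 family cytokine Il24 from 767 ± 96.1 to 1.29 ± 0.712 (603-fold). Gcnt4, a glycosyltransferase, had no count in Tfh5 and was at least 234-fold lower. The 10 with the highest were Il17f, Il17a, Daw1, Adam12, Ppp1r14c, Gja5, Ccl20, Cd33, Rasgrp3 and Nav2. Nav2, a neuron navigator protein, rose from 0.219 ± 0.182 to 108 ± 11.8 CPM (488-fold) and the sialic acid receptor Cd33 from 0.0581 ± 0.0326 to 36.8 ± 7.18 (554-fold). Ppp1r14c, a phosphatase inhibitor, had no count in Th1 and was at least 265-fold higher. Adjusted p-values of these 20 genes ran from 8.33e-21 to 5.16e-11.

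Of 23 Th1 genes, 21 fell and 2 rose (camera adjusted p = 2.51e-08, adjusted p = 0.0197 with an estimated correlation), with Nkg7 75.3-fold lower and the chemokine receptor Cxcr6, one of those that rose, 11.8-fold higher. All 18 interferon-γ response genes fell (camera adjusted p = 6.42e-10, adjusted p = 0.0197 with an estimated correlation), with Cxcl10 30.9-fold and Gbp4 29.7-fold lower. All 15 IL-2 and STAT5 response genes fell (camera adjusted p = 2.05e-08, adjusted p = 0.0228 with an estimated correlation), with Lta 18.9-fold lower. Of 26 cell cycle genes, 25 fell (camera adjusted p = 5.88e-08, adjusted p = 0.0452 with an estimated correlation), with Tk1 3.42-fold and Plk1 2.68-fold lower, and of 18 unfolded protein and amino acid stress genes, 13 fell and 1 rose (camera adjusted p = 0.0043, adjusted p = 0.0452 with an estimated correlation), with Asns 2.67-fold lower. All 20 glycolysis genes fell (camera adjusted p = 2.51e-08, adjusted p = 0.0778 with an estimated correlation), with Hk2 12.01-fold and Slc2a1 4.98-fold lower. The type I interferon list had 19 of 20 lower and none higher (camera adjusted p = 2.58e-08, adjusted p = 0.0639 with an estimated correlation), with Usp18 15.6-fold lower, and the cholesterol list 16 lower and 1 higher of 21 (camera adjusted p = 0.000338, adjusted p = 0.105 with an estimated correlation), with Fdps 3.63-fold lower. Of 21 follicular helper genes, 15 rose and 6 fell (camera adjusted p = 0.00473, adjusted p = 0.238 with an estimated correlation), with Pou2af1 268-fold and Tox2 288-fold higher. Of 20 Th17 genes, 13 rose and 6 fell (camera adjusted p = 0.0044, adjusted p = 0.177 with an estimated correlation), with Ccl20 773-fold higher, or 1260-fold without Th1 replicate 2. In the TGF-β and SMAD list 14 of 21 rose and 7 fell (camera adjusted p = 0.044, adjusted p = 0.177 with an estimated correlation, 0.0547 by the first test without Th1 replicate 5 and 0.0504 with replicate number as a block), with Ldlrad4 22.1-fold higher and Cdkn1a 13.8-fold lower.

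Lists that did not pass camera here included Th2 and Th9 genes (3 up, 8 down of 11, camera adjusted p = 0.058, adjusted p = 0.121 with an estimated correlation, 0.0468 by the first test without Tfh5 replicate 1), regulatory T cell genes (5 up, 10 down of 18, camera adjusted p = 0.398, adjusted p = 0.704 with an estimated correlation), with Nt5e 243-fold higher and Tnfrsf18 6.4-fold lower, and genes linked to c-Maf (5 up, 5 down of 10, camera adjusted p = 0.426, adjusted p = 0.693 with an estimated correlation), with Il23r 3.57-fold lower. IL-6 and STAT3 genes gave 8 up and 5 down of 14 (camera adjusted p = 0.311, adjusted p = 0.704 with an estimated correlation), naive and memory genes 8 up and 5 down of 15 (camera adjusted p = 0.146, adjusted p = 0.326 with an estimated correlation), with Klf2 20.4-fold higher and Bcl2 9.37-fold lower, and inhibitory receptor genes 11 up and 5 down of 17 (camera adjusted p = 0.246, adjusted p = 0.697 with an estimated correlation), with Nr4a1 4.48-fold higher. Chemokine receptors and integrins gave 12 up and 10 down of 25 (camera adjusted p = 0.452, adjusted p = 0.574 with an estimated correlation, median -0.12 and mean 0.43). Immediate early and heat shock genes gave 6 up and 7 down of 15 (camera adjusted p = 0.739, adjusted p = 0.821 with an estimated correlation), or 8 down adjusted over the list alone, the only list in this comparison where that adjustment changed a count, with Fos 5.97-fold higher. Mitochondrially encoded genes gave 6 up and none down of 8 (camera adjusted p = 0.124, adjusted p = 0.693 with an estimated correlation), with mt-Nd1 1.44-fold higher. With GC-content correction the log2 fold change of mt-Nd1 was 0.26 ± 0.13 in place of 0.52 ± 0.14, and the smaller change no longer passed (adjusted p = 0.0773, within 0.000133 to 0.766 over alternatives). Nuclear and histone transcripts gave 1 down and none up of 6 (camera adjusted p = 0.861, adjusted p = 0.933 with an estimated correlation, median 0.04 and mean -0.47), with Malat1 at 535 ± 164 against 553 ± 17.4 CPM.

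Among markers of other cell types, B cell markers gave 2 up and 2 down of 11 (camera adjusted p = 0.898, adjusted p = 0.945 with an estimated correlation, median 0.28 and mean -0.32), with Ighm 5.13-fold higher, and monocyte, macrophage and dendritic cell markers 2 up and 4 down of 7 (camera adjusted p = 0.125, adjusted p = 0.466 with an estimated correlation), with Cd74 25.4-fold and H2-Ab1 19.2-fold lower. The median of the latter was -4.27, or -2.74 with the 2 genes at the count floor set to their bound. CD8 T cell and NK cell markers gave 1 up and 3 down of 6 (camera adjusted p = 0.269, adjusted p = 0.365 with an estimated correlation), with Klrd1 4.42-fold higher. Of the 4 γδ receptor genes, 2 rose and none fell, with Trdc 2.1-fold higher. Ly6g was 1.73-fold lower, and Itga2b was at 1.36 ± 0.504 against 0.576 ± 0.307 CPM (adjusted p = 0.0193). That call was lost without Tfh5 replicate 5 (0.0672) or Th1 replicate 2 (0.0557) and with no filter on low counts (0.0517), at log2 fold changes of 0.98 to 1.21 against 1.23 as reported. Camera passed 11 of 24 lists, and 5 held with an estimated correlation (Th1, interferon-γ, IL-2 and STAT5, cell cycle and unfolded protein lists).

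Genes were counted as set apart in a group when they differed by at least 2-fold in the same direction from both other groups. Tfh5 had 2169 such genes, 995 higher and 1174 lower. The 5 highest by the fixed rule were Daw1, Gja5, Il17a, Ccl20 and Myo3b, and the 5 lowest Il3, Ifi211, Tnc, Ubd and Gcnt4, all under 0.06 CPM in Tfh5. Th1 had 1160, 762 higher and 398 lower. Onecut2, Stra6, Lrp1, Chl1 and Cd83 were the highest, with Lrp1, an endocytic receptor, at 56.4 ± 8.73 CPM against 1.19 ± 0.37 and 0.431 ± 0.291, and Pou2af1, Tox2, Rasgrp3, Ppp1r14c and Nav2 the lowest. TfhA had 483, 252 higher and 231 lower. Vat1l, Il33, Moxd1, Ndst3 and Rtp4 were the highest, with Moxd1 at 62.1 ± 6.85 CPM against 1.42 ± 0.847 in Th1 and 1.12 ± 0.96 in Tfh5. The lowest were Pdpn, Prr5l, Il10, Pkib and Calca, with the glycoprotein podoplanin gene Pdpn at 0.42 ± 0.249 CPM against 14.8 ± 1.3 in Th1 and 83.4 ± 10.7 in Tfh5.

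Because each group's libraries enter both of its comparisons, the counts were set against references. Independent lists of the same sizes would share 436.3 genes for Tfh5, 206.6 for TfhA and 254 for Th1. Data simulated with no effect in any gene gave 0 in each of 20 runs. Almost no gene can pass both comparisons in such data. That value therefore does not measure what shared libraries add when many genes differ. With the group's own libraries split so that each comparison used different ones, the median was 1994.5 genes for Tfh5 (1900 to 2036 over 20 splits), 411.5 for TfhA (396 to 425 over 6 splits) and 1061 for Th1 (995 to 1085 over 20 splits).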

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

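The tests of GC content, of transcript length and of 23 Tfh5 genes in Th1 replicate 2 were fixed before their results were seen, while the tests of parts of these 23, of abundant Tfh5 genes, of other genes high in that library and of γδ T cells and B cells were chosen only after the result was seen. Values came under review when the highest or lowest library of a group lay far from the others by Dixon's ratio at the 95% level. This was tried on 471 sets of library values, mostly CPM of 154 named genes, and 47 exceeded it, where about 23.6 are awaited by chance at 1 in 20. That rate does not hold for genes with almost no counts, where a single count among libraries with 0 always exceeds the limit. Such 1-count values included Gja5 in Th1 replicate 2, Gzmc and Ubd in Tfh5 replicate 1, and Cxcl11 and Fbn1 in Tfh5 replicate 3. The number above 23.6 is therefore not read as an excess.

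Th1 replicate 2 held the interleukin-17 genes Il17f at 8.6 CPM (0.624 to 0.907 in the other 4 Th1 libraries) and Il17a at 0.971 CPM (0 to 0.0756), which would be 0.239% and 0.29% of their Tfh5 levels. Over 23 other genes found almost only in Tfh5, 66 counts were seen in this library where the other Th1 libraries lead to 71.2 and Tfh5 material would add 31.4, a share of -0.0273% of the Tfh5 level. Their sum of 4.58 CPM lay within the 4.23 to 5.44 of the other Th1 libraries, which by the limit set beforehand argues against Tfh5 material. That limit took the Th1 level of these genes to be alike in all 5 libraries, and sums over 2 parts of them, made afterwards, show that it was not. The 14 genes under 20 CPM in Tfh5, to which such material would add 6.3 counts, summed to 2.15 CPM against 3.26 to 4.46, while the other 9, to which it would add 25.1, summed to 2.43 CPM against 0.436 to 1.45 (35 counts where 14.2 are awaited without it). A share fitted over all 23 in proportion to their Tfh5 levels was 0.175% (0.072 to 0.232 over resampled genes), short of the 0.239% of Il17f, against -0.074% (-0.102 to -0.074) in Th1 replicate 1, -0.07% (-0.096 to 0.167) in replicate 3, -0.027% (-0.098 to 0.074) in replicate 4 and 0.072% (0.012 to 0.195) in replicate 5, of which the last 3 intervals overlap that of replicate 2. So the sum is not taken to exclude Tfh5 material. Over the 6 genes with at least 50 CPM in Tfh5 and at most 0.5 CPM in the other Th1 libraries (Ccl20, Daw1, Gcnt2, Iglon5, Myo3b and Nav2, the same 6 with that limit on the mean of all 5), 40 counts were seen against 15 awaited, a share of 0.215% (95% counting interval 0.117 to 0.339). The same rule, with the genes chosen anew for each library, gave Th1 replicate 5 a share of 0.118% (0.025 to 0.237) over 7 genes (the 6 and Agap1) without a rise of Il17f, so an excess of this kind is no proof of such material, and the other 3 Th1 libraries -0.083 to -0.074% over 6 or 7 genes. Ldlrad4 and Moxd1, also high in Th1 replicate 2, would need 7.1% and 167% of their Tfh5 levels, so a trace of this size does not account for them, and a cause of those 2 values was not tested. Gja5, high there as well, would need 0.277%, close to the shares of Il17f and Il17a, but rests on 1 count. With the planned test against it and the later ones partly for it, a trace of Tfh5 cells, RNA or reads may account for the interleukin-17 counts and is not settled, and a few cells of the Th1 culture that expressed these genes, which was not tested, stay open too.

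TfhA libraries held transcripts of the γδ T cell receptor, such as Trdc at 53.5 ± 19.3 CPM against 5.54 ± 1.49 in Th1 and 11.8 ± 3.19 in Tfh5, and of B cells, such as Jchain at 2.22 ± 0.918 against 0.0721 ± 0.0729 and 0.164 ± 0.171 CPM, although naive CD4 cells had been isolated and the cultured cells were sorted, which would remove both cell types. Of these lists, all 4 tested γδ genes and all 11 tested B cell genes also had counts in Th1 and in Tfh5, and none is in another list. Sox13, Blk and Zbtb16, the γδ markers outside the receptor loci, summed to 0.374 CPM in TfhA, 0.719 in Th1 and 0.501 in Tfh5, but the 15 counts behind the TfhA value are too few to argue against γδ T cells. Of 3 genes abundant in B cells and low in Th1, 2 were higher in TfhA (Cd79b and Igkc) and Cd79a was not called (adjusted p = 0.0915), and Cd74 (60.5 ± 17.8 CPM against 175 ± 22.9) and H2-Ab1 (25.6 ± 5.61 against 75.9 ± 7.09) were lower in TfhA than in Th1, whose own high level hides a small share of B cells. A few γδ T or B cells in the sort, and transcription of these loci by the TfhA cells themselves, which was not tested, may each account for the pattern and stay open.

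Th1 replicate 1 and TfhA replicate 2 departed from their groups in the same genes (correlation of deviations 0.331 across 12656 genes, which are not independent replicates), and Th1 replicate 1 and TfhA replicate 5 in opposite ones (-0.374), against sizes of at most 0.155 for all other pairs across groups. These deviations followed the GC content of transcripts, with rank correlations of 0.652, 0.482 and -0.522 in Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5. With the GC trend removed the first correlation was 0.131, between the limits set beforehand (under 0.1 if GC were the cause, over 0.2 if not), and the second -0.177, so GC content may account for part of the pattern and is not settled as its whole cause. Transcript length is argued against, since the correlation stayed at 0.324 with the length trend removed. The labels name no library batch, and no biological explanation was tested.

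The remaining values are given in CPM with the range of the other libraries of the group in parentheses, except that Tfh5 replicate 5 had a total of 13.32 (in million-count units) against 9.77 to 10.6. Th1 replicate 1 took 11 of the 47 values, Tfh5 replicate 1 took 8, Tfh5 replicate 4 took 7, Th1 replicate 2 took 5 and no other library over 4. Th1 replicate 1 stood above the rest of its group with Aldoa at 3599 (2574 to 2851), Ccr7 at 979 (724 to 772), Irf8 at 408 (296 to 306), Lss at 44.4 (37 to 38.9), Pmepa1 at 99 (73.2 to 77.9), Tbx21 at 306 (218 to 242), Tk1 at 48 (39.95 to 42.2) and Tnfrsf18 at 538 (404 to 439). It stood below its group with Cd33 at 0 (0.0693 to 0.0761), Klrk1 at 29.7 (43.2 to 44.7) and mt-Nd1 at 5476 (7293 to 7791). Th1 replicate 2 stood above the rest of its group with Gja5 at 0.0693 (0), Ldlrad4 at 11 (2.27 to 4.51) and Moxd1 at 2.91 (0.832 to 1.21). Th1 replicate 3 stood above the rest of its group with Hsp90aa1 at 81.8 (69.8 to 72.6). It stood below its group with Dgkk at 7.64 (8.22 to 8.29). Th1 replicate 4 stood above the rest of its group with Gcnt4 at 19.6 (9.75 to 12.2) and Postn at 0.139 (0).

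TfhA replicate 1 stood above the rest of its group with Daw1 at 0.151 (0), Peli2 at 0.757 (0.212 to 0.256) and Postn at 0.0757 (0). TfhA replicate 2 stood above the rest of its group with Tox2 at 4.09 (2.17 to 2.33). TfhA replicate 4 stood below its group with Tnfsf8 at 211 (308 to 328). Tfh5 replicate 1 stood above the rest of its group with Dgkk at 1.24 (0 to 0.102), Gzmb at 16.1 (1.61 to 3.74), Gzmc at 0.0952 (0), Itga4 at 106 (73.7 to 78.8) and Ubd at 0.0952 (0). It stood below its group with Gpr83 at 5.05 (10.9 to 12.1), Hsp90aa1 at 12.3 (25.6 to 28) and Slc2a1 at 29.8 (43.1 to 46.3). Tfh5 replicate 2 stood above the rest of its group with Il33 at 0.408 (0 to 0.0952) and Psat1 at 87.6 (76.5 to 79.5). Tfh5 replicate 3 stood above the rest of its group with Cxcl11 at 0.0944 (0), Fasl at 2.83 (0.816 to 1.33) and Fbn1 at 0.0944 (0). It stood below its group with Entpd1 at 2.45 (5.81 to 6.83). Tfh5 replicate 4 stood above the rest of its group with Cxcl10 at 1.9 (0.476 to 0.849), Foxo1 at 675 (619 to 634) and Pdpn at 102 (76.5 to 82). It stood below its group with Daw1 at 70.5 (94.3 to 101), Rasgrp3 at 19.7 (26.7 to 28.2), Stra6 at 0 (0.0747 to 0.102) and Tnfrsf18 at 56.1 (71.6 to 75.5).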

How the results depend on the processing

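The GC-content correction and the fit without Th1 replicate 1, TfhA replicate 2 and TfhA replicate 5 were chosen only after the data were seen, and all other alternatives were planned. Calls numbered 6584 to 7917 for Tfh5 with TfhA (7520 as reported), 4393 to 6124 for TfhA with Th1 (5852) and 7118 to 9166 for Tfh5 with Th1 (8440) over scaling, filters, tools, replicate block, 2-group fits, GC correction and the fit without 3 libraries, and 7008 to 7633, 5220 to 6146 and 8031 to 8633 with each library left out. The lowest of these counts come from fits with fewer genes tested or fewer libraries, and no gene called both ways changed sign under any of them. A minimum fold of 1.5 is a stricter question and gave 3457, 1740 and 4221. The stricter filter on low counts, which tests 10553 genes, lowered the genes with a change of at least 2-fold to 425 higher and 711 lower in TfhA against Th1 and 1323 lower in Tfh5 against Th1, and the genes set apart to 295 in TfhA and 742 in Th1. Without single libraries the genes set apart numbered 2113 to 2233 for Tfh5, 453 to 486 for TfhA and 1079 to 1200 for Th1.

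Gene lists depended on the test, and the cause was not tested. With an estimated correlation 3, 2 and 5 lists passed in the order of comparisons above, and 22, 14 and 22 by fry, which does not compare a list with other genes. By fry the regulatory T cell list in Tfh5 against TfhA had an adjusted p of 0.0361 in the direction opposite to camera, within 0.0361 to 0.999 over its alternatives. Without single libraries 12 to 15, 6 to 8 and 10 to 12 lists passed camera.

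Of 6403 alternative values of 257 gene results, 6334 kept direction and side of the threshold, 38 lost the call, 17 gained it and 14 changed direction, and 226 of the 257 results kept both throughout. The test against a minimum fold ended 19 of the 38. With replicate number as a block, calls numbered 7258, 5521 and 8285, and Foxp3 in 2 comparisons and Bcl6 in 1 passed and the camera calls of 2 lists were lost, as given beside these results. The direction changes were all in results that did not pass, with log2 fold changes near 0. Itga2b in TfhA against Th1 (-0.13) was 0.11 with GC correction, 0.10 without the 3 libraries and -0.37 to 0.17 without single ones. Foxp3 in TfhA against Th1 (-0.13) was 0.34 without the 3 libraries and -0.42 to 0.19 without single ones. Without single libraries, Cxcr5 in TfhA against Th1 (0.14) ran from -0.044 to 0.40, Ccr7 in Tfh5 against TfhA (0.02) from -0.055 to 0.11 and Malat1 in Tfh5 against Th1 (-0.05) from -0.186 to 0.10. The cause of these moves was not tested. DESeq2 gave no adjusted p for Gzmb and Il17f in comparisons with TfhA and for Il17f in Tfh5 against Th1, and genes under a filter have no value there.

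With all genes in place of the 500 most variable, the first 2 components carried 64.4 and 18.2% of variance. Deviations of libraries that share a replicate number had correlations of -0.048 to 0.155 over 13 pairs, 1 of them over 0.1, against -0.368 to 0.327 over 52 other pairs, and 5 of the 14 libraries correlated best with their own number. On the 500 genes most variable within groups they were -0.002 to 0.177, 4 of them over 0.1, against -0.147 to 0.165, and 9 of the 14 libraries correlated best with their own number. This is a hint from the data that some libraries with the same number go together, but not every pair was over 0.1 and the labels do not say what a number stands for, so the numbers were not used to pair libraries. Depth limits genes with few counts: a gene with 0 counts over a group has a bound and no fold. In simulated data 76 to 82% of 2-fold and 51 to 55% of 1.5-fold changes were recovered. Far fewer genes were changed there than passed in the real data, so these shares are not the recovery in the real data.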

Other observations

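The test of interferon response genes against the Ifng level was chosen only after the result was seen, while the regroupings of libraries and the tests of genes with a count were fixed before. Among further genes with the 10 highest or lowest fold changes of a comparison, Th1 libraries held Insl5, an insulin-like peptide hormone, at 19.8 ± 4.45 CPM against 0.185 ± 0.109 in TfhA, and Casr, the calcium-sensing receptor, at 10.1 ± 1.12 against 0.164 ± 0.16 in TfhA and 1.69 ± 1.13 in Tfh5. Casr was 52.8-fold lower in TfhA than in Th1, or 93.1-fold without TfhA replicate 1. Onecut2, a homeodomain transcription factor, stood at 51.4 ± 5.73, 0.841 ± 0.162 and 0.0829 ± 0.0922 CPM in Th1, TfhA and Tfh5. Sema3b, a secreted semaphorin, stood at 62.5 ± 7.26, 1.63 ± 0.474 and 0.126 ± 0.0792 CPM, and Mt3, a metallothionein, at 47.5 ± 8.84, 3.67 ± 1.4 and 0.0789 ± 0.108 CPM in the same order. Each of these 3 genes was lower in TfhA than in Th1 and lower again in Tfh5 than in TfhA.

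Other genes were highest in a follicular helper culture. Dgkk, a diacylglycerol kinase, was at 97.8 ± 17 CPM in TfhA, 8.13 ± 0.278 in Th1 and 0.287 ± 0.534 in Tfh5, and 1 library, Tfh5 replicate 1, held most of the Tfh5 counts (344-fold lower in Tfh5 than in TfhA, 1760-fold without it). The latter fold is imprecise, since Dgkk was at 0 to 0.102 CPM in the other Tfh5 libraries. Vat1l was at 36.9 ± 13.8 CPM in TfhA and under 1 CPM in both other groups. Akr1c18, which inactivates progesterone, rose 44.3-fold from Th1 to TfhA (0.972 ± 0.748 to 42.4 ± 16.9 CPM), and Dhrs9, a retinol dehydrogenase, 34.6-fold (0.307 ± 0.207 to 10.6 ± 3.23 CPM). Peli2, a ubiquitin ligase of Toll-like receptor signalling, was highest in Tfh5 (138 ± 16.3 CPM), with 3.91 ± 1.08 in Th1 and 0.361 ± 0.265 in TfhA. Adam12, a metalloprotease, reached 42.2 ± 2.33 CPM in Tfh5 with 2 counts in Th1, a ratio of 1500-fold (95% counting interval 415 to 12400).

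The counts were set against random regroupings of the libraries, with a limit of fewer than 5 in 100 fixed beforehand. Of 100 of the 126 possible splits of the 9 libraries of Tfh5 and TfhA, 1, the real one, called 7520 genes and the next highest 5240, in which all but 1 of the libraries had changed places. For TfhA and Th1 the real split called 5852 and the next highest 3475, also with all but 1 library exchanged, and it was again 1 of 100. For Tfh5 and Th1 the real split called 8440, 1 of 100, and every other 0. All 3 counts were thus larger than those of the random splits drawn. A split that mixes the cultures adds their difference to the spread within its groups, which lowers its calls. The splits therefore say little about the size of the real counts, and whether the libraries are independent is not given. The numbers of lists past camera behaved otherwise: 6 of 100 splits gave as many as the 13 of Tfh5 with TfhA (highest other 13) and 5 of 100 as many as the 8 of TfhA with Th1 (highest other 8), so chance is not excluded for these numbers. For the 11 of Tfh5 with Th1 it was 4 of 100, just under the limit of 5 in 100, and the highest other was also 11. This number is therefore not read as excluding chance either. Random splits passed a median of 4, 5 and 6 lists in these comparisons, so a single camera call may be weaker evidence than its adjusted p reads. By how much cannot be told, since these splits held the 2 cultures in unequal shares and can keep part of their difference. In a split of Tfh5 and Th1 with 11 lists, the group named Th1 held 1 Th1 and 4 Tfh5 libraries. In one of Tfh5 and TfhA with 13, the group named TfhA held 1 TfhA and 3 Tfh5 libraries. Of 100 regroupings of all 14 libraries, 1 gave as many genes set apart as Tfh5 (2169, highest other 0) and 1 as many as Th1 (1160, highest other 14). For TfhA (483) it was 2, with 1404 in a regrouping whose group of that name held 4 Tfh5 libraries. All 3 shares were under the limit of 5 in 100, and what is said above of mixed groups holds here too. Since a random regrouping exceeded the 483 of TfhA by far, chance is not taken as excluded for that count. Why it gave 1404 was not tested, though Tfh5 stands farthest from the rest in these samples.

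Fewer genes had a count in Tfh5 libraries (14481 ± 307.2) than in TfhA (15321.2 ± 351.2) and Th1 (15726.4 ± 301.9). Depth is argued against: with every library thinned to 8805921 counts, Tfh5 stayed below TfhA by a mean difference of -786.4 genes, with no overlap (exact permutation test, two-sided, p = 0.0159, 0.0239 adjusted over 9 tests). A larger share of counts in a few abundant genes is argued against too: without mitochondrial genes and the 100 most abundant genes of each library the difference was -776.1 (exact permutation p = 0.00794, the smallest that 126 regroupings can give, 0.0143 adjusted). A smaller set of expressed genes in cells cultured with TGF-β remains a candidate explanation, tested on the same libraries it was seen in, and RNA content per cell is not given in the sources used here.

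Type I interferon response genes were lower in Tfh5 than in TfhA, and so was Ifng, which raised the hypothesis that the list follows the Ifng transcript. From Th1 to TfhA, where Ifng changed by -5.18 on the log2 scale, the median of the 20 list members was 0.26 (SD of members 1.45), while from TfhA to Tfh5, with -4.34 for Ifng, it was -3.96. A response of this list in proportion to the Ifng transcript alone is argued against, since the list would have fallen by a similar amount in the first step. Th1 and TfhA cultures differed in more than Ifng, so the test cannot exclude Ifng as a part of what sets the list. The interferon-γ list fell in both steps, with medians of -1.06 from Th1 to TfhA and -1.21 from TfhA to Tfh5. Interferon protein and type I interferon genes were not analysed here.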
